A study of Homo sapiens with 2 samples.

How the data were processed

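Adipose-derived commercial mesenchymal stem cells were measured in 2 libraries, untreated and with TGFB1, per the labels. Cells were detached with trypsin, frozen and sent for 10x single-cell sequencing, per the labels' protocols. The submitters' processing notes name Cell Ranger 9.0.1, Seurat and the GRCh38 build, without stating their roles. The annotation is not given in the sources used here. The matrix deposited by the authors holds raw UMI counts per gene and cell for both libraries together, with 38606 genes and 20656 cells. The cell table deposited by the authors gives counts of UMIs and genes per cell, the percent of UMIs from mitochondrial genes, and 2 other columns, the library name and the cluster number at resolution 0.4. Cell sums of the matrix equalled the UMI totals of the table in all 20656 cells. The lowest gene count was 505 in untreated and 502 in TGFB1 cells, and the highest mitochondrial share was 5.00%, so cells appear to have been filtered on both before deposit. Genes are named by symbol only; 12962 names are Ensembl identifiers and 23208 names were found in GENCODE release 29 (GRCh38), which was used for gene positions. Reads shared between near-identical genes or overlapping antisense genes could not be assessed from counts.

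UMIs were summed over all cells of a library and divided by the library total to give CPM. Ratios are TGFB1 over untreated with exact conditional binomial (Clopper-Pearson) 95% intervals, sums carry exact Poisson intervals and shares of cells exact binomial ones. With 1 library per group no test of the treatment is possible: no p-value was computed, cells were not used as replicates, and an interval compares these libraries and not the conditions. A count of 0 would allow up to 3 UMIs, or 0.0178 CPM in the untreated and 0.0144 CPM in the TGFB1 library. DESeq2 was not used, and edgeR 4.0.16 was used only for TMM factors (1.06 and 0.948). Size factors by the median of ratios were 1.07 and 0.936.

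The design, the rule for named genes, 35 gene lists, the cell type markers and most alternatives were fixed before the data were examined. Named genes were the 12 largest and 12 smallest ratios among genes at 20 CPM or more in either library, all measured members of the interleukin 6 family, up to 4 members of each other list with the largest absolute log2 ratio, and the 10 highest ratios between cells with and without IL11. The 10 lowest of these ratios were named after their values were seen. Clone-style, Ensembl-only, mitochondrial and ribosomal protein names were left out of the ranking, and XIST, TSIX and Y-linked genes were left out of all results. Where 5 or fewer members of a list passed 1.5-fold in a direction, those outside the rule were named too, after their values were seen. Some genes that the rule names are not reported here. List members counted from 5 CPM in either library, as higher or lower from 1.5-fold. The median of a list was placed among 10000 random lists of the same size, matched in 20 bins of mean expression. The lists covered TGFB and bone morphogenetic protein signalling, contractile and adhesion genes, matrix, inflammation and interferon, stromal identity, lineages, growth factors, Wnt, Notch, the cell cycle, stress, metabolism and markers of other cell types.

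To compare shares of cells across depths, each cell was thinned to 7500 UMIs without replacement, which kept 7646 untreated and 9330 TGFB1 cells. Clusters are the authors', and were named only where at least 3 markers fixed beforehand were detected. The TGFB1 library was also clustered on its own without IL11, and the untreated library without genes differing by 1.5-fold or more, with scanpy 1.11.5 (2000 variable genes, 30 components, 15 neighbours, Leiden). Scrublet, run per library, marked 0 of 8101 and 0 of 12555 cells. It is taken not to have worked, so any doublets in the deposited cells were kept. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.

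The steps were tested on simulated data for the comparison of TGFB1 with untreated cells, with Poisson counts for 10927 genes of which 200 were changed. All 100 genes changed 4-fold passed 2-fold, 0 of 100 changed 1.5-fold did, and no unchanged gene did. The intervals held the simulated ratio in 95.1% of genes. A list of 20 genes raised 4-fold lay at percentile 100, and 20 unchanged lists lay between 1.90 and 89.5. The simulated counts followed the model that the intervals assume, so this checked the calculation only. It held no difference in handling between libraries, no spread between cells and no correlation within lists. It therefore cannot tell how many differences would arise without TGFB1. Alternatives were other scalings, an equal weight for each cell, thinning, a minimum of 1 or 20 CPM, a cell filter of 1000 genes and 10% mitochondrial UMIs, and leaving out cells with an MKI67 or TOP2A UMI. Leaving out cluster 5 or clusters 7, 9 and 10, clustering at resolution 0.5, and counting clusters of any size were added after seeing the data.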

Results

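Interleukin 11 (IL11) is a secreted cytokine of the interleukin 6 family, and the study asks about stromal progenitor cells whose effect on melanoma depends on it. Transforming growth factor beta 1 (TGFB1) is a secreted factor that signals through SMAD transcription factors and activates fibroblasts. Commercially supplied human mesenchymal stem cells from adipose tissue were grown close to confluence and kept overnight without serum. One culture was then left untreated and the other received TGFB1 at 10 ng/mL for 24 hours. Single-cell transcriptomes were counted as unique molecular identifiers (UMIs), in 1 library per condition. The untreated library held 8101 cells and 169011524 UMIs, with a median of 19249 UMIs and 4888 genes per cell. The TGFB1 library held 12555 cells and 208991941 UMIs, with a median of 15134 UMIs and 4101 genes per cell. Mitochondrial transcripts made up a median of 2.66% of a cell's UMIs in the untreated library and 2.49% in the TGFB1 library. Ribosomal protein genes took 15.3% and 13.8% of all UMIs. The comparison of the libraries asks which transcripts differ after exposure to TGFB1, and which cells carry IL11. No difference given here has a replicate check. Intervals are 95% intervals that cover counting error only.

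Among genes at 20 CPM (counts scaled to the library total) or more in either library, the largest ratios were those of TSPAN13, IL11 and KANK4. TSPAN13, a tetraspanin, was 46.5-fold higher in the TGFB1 library (40.2 to 54.1), at 1.09 CPM in the untreated and 50.9 CPM in the TGFB1 library. IL11 was 46.0-fold higher (42.2 to 50.2). KANK4, of a family of adhesion and cytoskeleton adaptors, was 43.7-fold higher (37.4 to 51.5). LDLRAD4 and PMEPA1, both inhibitors of TGFB signalling that bind SMAD proteins, were 18.8-fold and 8.35-fold higher. The other genes among the 12 with the largest ratios were TSPAN2 (16.8-fold), the proteoglycan xylosyltransferase XYLT1 (7.73-fold), the cyclin-dependent kinase inhibitor CDKN2B (7.65-fold), the progenitor marker PI16 (7.43-fold), MAMDC2 (7.19-fold), DCLK2 (7.10-fold) and the neuropeptide gene GAL (6.71-fold). In GENCODE release 29 (GRCh38), TSPAN13 lies on chromosome 7 from 16753535 to 16784536 and KANK4 on chromosome 1 from 62236979 to 62319414.

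At the other end of these genes, FGF13, an intracellular homologue of the fibroblast growth factors, was 32.8-fold higher in the untreated library (29.5 to 36.6), at 54.9 CPM against 1.67 CPM. It lies on chromosome X from 138614731 to 139222777. The syntrophin gene SNTG1 was 30.4-fold higher without TGFB1 and PLAAT4, an acyltransferase, 17.7-fold higher. The urea transporter gene SLC14A1 (16.0-fold), the claudin gene CLDN11 (14.5-fold), the soluble pattern recognition gene PTX3 (13.9-fold) and adrenomedullin, ADM (11.1-fold), followed. Hepatocyte growth factor, HGF, was 10.5-fold higher in untreated cells and the integrin gene ITGB8 10.1-fold. The interferon-induced gene IFIT3 (9.95-fold), the kinase gene DCLK1 (9.53-fold) and the long non-coding RNA LINC02511 (9.15-fold) completed the 12 smallest ratios.

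Among 10927 genes at 5 CPM or more in either library, 395 (3.61%) were at least 2-fold higher and 661 (6.05%) at least 2-fold lower with TGFB1. The median log2 ratio over these genes was -0.10. This split depended on the scaling: with TMM factors 529 genes were higher and 490 lower, and with median-of-ratios factors 574 were higher and 464 lower. These factors moved the median over all genes by 0.16 and 0.20, and the medians of the gene lists by 0.15 to 0.39 and 0.19 to 0.43. The log2 values below are relative to the CPM scale, and list medians near 0 move most in proportion.

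IL11 had the largest ratio of its cytokine family, at a log2 ratio of 5.52, and LIF was next at 3.36. IL11 lies on the minus strand of chromosome 19 from 55364389 to 55370463 in GENCODE release 29. It had 527 UMIs (3.12 CPM) in the untreated library and 29952 UMIs (143 CPM) in the TGFB1 library. LIF, another ligand of the family, was at 1.48 CPM untreated and 15.2 CPM with TGFB1. Lower with TGFB1 by at least 1.5-fold were the feedback inhibitor SOCS3 (10.2 and 5.38 CPM), the shared receptor subunit IL6ST (318 and 182 CPM) and the receptor gene LIFR (20.8 and 13.1 CPM). Of the 14 members measured, 8 differed by less than 1.5-fold. They were the receptor of IL11 itself, IL11RA (19.1 and 12.9 CPM), CTF1 (14.0 and 9.46 CPM), JAK1 (278 and 229 CPM), JAK2 (20.8 and 18.5 CPM), OSMR (92.9 and 90.0 CPM), STAT3 (92.5 and 102 CPM), CLCF1 (7.19 and 8.56 CPM) and IL6 (86.8 and 128 CPM). The median of the family was -0.11, and 0.05 with TMM factors, so it had no direction that held across scalings. It was -0.05 over members at 20 CPM or more.

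Most treated cells held IL11 transcripts and few untreated cells did. At least 1 IL11 UMI was found in 5.55% (5.07 to 6.08) of untreated cells and 64.0% (63.2 to 64.9) of TGFB1 cells. After thinning to 7500 UMIs per cell, which left out 455 untreated and 3225 TGFB1 cells, the shares were 2.13% (1.82 to 2.48) and 52.1% (51.1 to 53.1). At that depth LIF was seen in 0.929% of untreated and 8.53% of TGFB1 cells, against 2.27% and 14.4% before thinning. IL11RA was seen in 13.6% and 9.38% of thinned cells (31.0% and 18.1% before) and IL6ST in 86.4% and 70.6% (94.8% and 81.1% before). IL6 was seen in 33.1% and 49.6% of thinned cells (52.7% and 64.2% before). These cultures hold no cell type known to lack IL11, so a background share from free RNA could not be measured. PTPRC, a leukocyte gene, was seen in 0.144% and 0.225% of thinned cells (0.395% and 0.558% before).

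**Figure D1:**
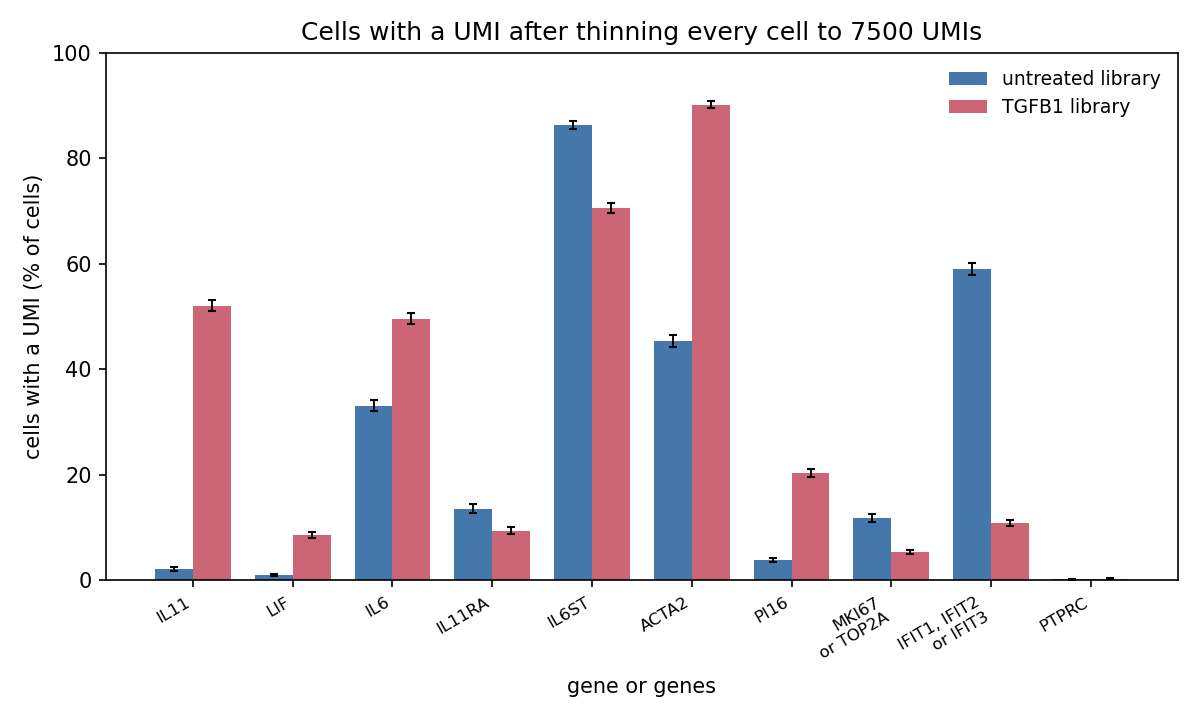
Percentage of cells with at least 1 UMI of each gene or gene group in the untreated and TGFB1 libraries, after every cell was thinned to 7500 UMIs. Bars are shares of 7646 untreated and 9330 TGFB1 cells, error bars are exact 95% binomial intervals for counting error, and IL11 goes from 2.13% to 52.1%.

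Genes that respond to SMAD signalling were higher as a group. Of 19 measured, 15 were at least 1.5-fold higher and none lower, with a median log2 ratio of 1.22. Besides LDLRAD4, PMEPA1 and CDKN2B, the oxidase gene NOX4 was at 16.5 CPM untreated and 88.2 CPM with TGFB1. Of 10 targets of bone morphogenetic protein signalling, 3 were higher (ID3 at 741 and 1764 CPM, BAMBI at 17.0 and 28.8 CPM, SMAD9 at 28.4 and 43.7 CPM) and none lower, with a median of 0.07, or 0.30 over members at 20 CPM or more. Among 22 ligands, receptors and activators of the TGFB pathway, 9 were higher and 4 lower, with a median of 0.23. The activin subunit INHBA was at 133 and 425 CPM. The 4 lower genes were ITGB8, the co-receptor TGFBR3 (65.3 and 10.6 CPM), SMAD3 (86.6 and 20.1 CPM) and the receptor TGFBR2 (380 and 181 CPM).

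Contractile genes were higher with TGFB1. Of 16 measured, 13 were at least 1.5-fold higher and none lower, with a median of 0.89. Smooth muscle actin, ACTA2, was at 202 and 1270 CPM and was seen in 45.4% of untreated and 90.2% of TGFB1 cells after thinning (69.0% and 94.5% before). The tropomyosin gene TPM1 was at 1457 and 7409 CPM, calponin CNN1 at 105 and 428 CPM and the adhesion gene TNS1 at 48.7 and 163 CPM. Targets of YAP and SRF, which respond to actin tension, had 7 of 19 members higher and 1 lower, with a median of 0.45. CCN2 was at 1015 and 3219 CPM and SRF itself at 9.08 and 19.9 CPM, whereas FOSL1 was the lower member at 24.96 and 12.71 CPM. Integrins and adhesion genes had 7 of 15 members higher and 1 lower, with a median of 0.57. ITGA1 was at 26.7 and 67.3 CPM, N-cadherin CDH2 at 466 and 1025 CPM and the lower member ITGA8 at 8.83 and 1.96 CPM.

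Matrix genes differed in both directions. Of 31 fibrillar and basement membrane genes, 12 were at least 1.5-fold higher and 4 lower, with a median of 0.46. COL7A1 was at 2.75 and 14.7 CPM, COL11A1 at 2.13 and 6.90 CPM, the proteoglycan versican, VCAN, at 473 and 1312 CPM and COMP at 347 and 909 CPM. The far more abundant COL1A1 (6862 and 9412 CPM), COL1A2 (7622 and 9179 CPM) and COL3A1 (1806 and 2109 CPM) differed by less than 1.5-fold. These collagens were looked at after their values were seen. The lower members were decorin, DCN (2010 and 771 CPM), FBN2 (471 and 204 CPM), lumican, LUM (599 and 294 CPM), and POSTN (304 and 194 CPM). Collagen-modifying enzymes had 6 of 19 members higher and none lower, with a median of 0.16 (0.09 after thinning), led by the prolyl hydroxylase P4HA3 (14.9 and 65.3 CPM) and the lysyl hydroxylase PLOD2 (104 and 294 CPM). Of 17 proteases and inhibitors, 4 were higher (ADAM19 at 41.6 and 156 CPM, TIMP3, ADAMTS6 and ADAM12) and 5 lower, with a median of 0.14. The lower ones were ADAMTS5 (27.3 and 3.10 CPM), ADAMTS1 (132 and 27.1 CPM), the plasminogen activators PLAT (41.6 and 7.16 CPM) and PLAU, and MMP1.

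**Figure D2:**
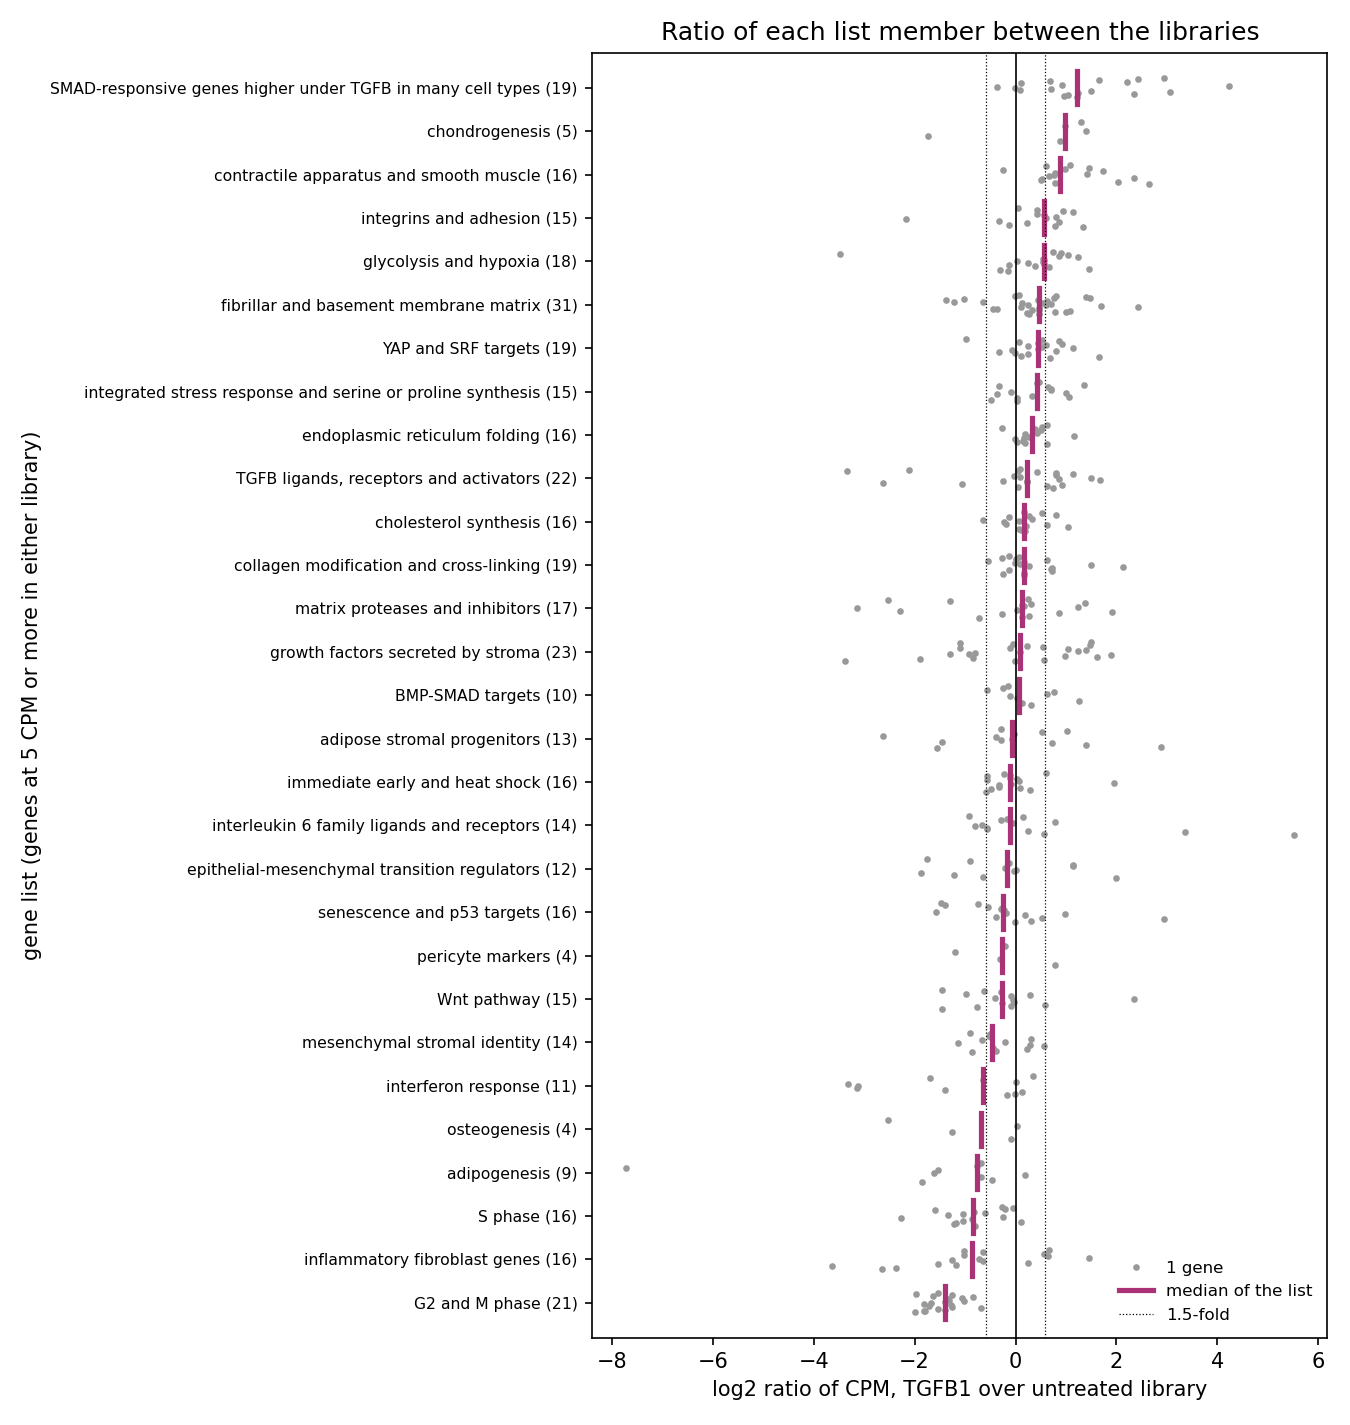
Log2 ratio of CPM (TGFB1 over untreated library) for each gene of the 29 lists with at least 3 genes measured, 1 point per gene, with the median of the list as a bar. List medians run from -1.40 for genes of G2 and M phase to 1.22 for SMAD-responsive genes; those of the interleukin 6 family, adipose progenitors, immediate early genes and pericyte markers change sign with TMM factors.

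Inflammatory and interferon genes were lower with TGFB1. Of 16 inflammatory fibroblast genes, 11 were at least 1.5-fold lower and 3 higher, with a median of -0.87. The median was -0.57 with TMM factors, -0.53 with median-of-ratios factors and -0.38 over members at 20 CPM or more. The chemokine CXCL6 was at 13.6 and 1.10 CPM, CXCL1 at 9.84 and 1.58 CPM, CXCL3 at 5.11 and 0.986 CPM and CXCL12 at 20.4 and 7.03 CPM. The higher members were the prostaglandin synthase PTGS2 (8.38 and 23.0 CPM), SAA1 (4.23 and 6.71 CPM) and HAS2 (66.9 and 104 CPM). Interferon-response genes had 6 of 11 members lower and none higher, with a median of -0.65, or -1.40 over members at 1 CPM or more. IFIT1 was at 69.9 and 7.93 CPM, IFIT2 at 40.9 and 4.73 CPM and IFITM1 at 77.3 and 23.9 CPM. A UMI of IFIT1, IFIT2 or IFIT3 was seen in 59.1% of untreated and 10.8% of TGFB1 cells after thinning (80.3% and 19.1% before).

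Most measured genes of the adipose lineage list were lower and those of the progenitor lists were mixed. Of 9 adipogenic genes measured, from a list of 22, 7 were lower and none higher, with a median of -0.76. The fat cell markers ADIPOQ, PLIN1, FABP4, LPL and CEBPA did not reach 5 CPM in either library. The fat cell regulator PPARG was at 21.5 and 5.96 CPM, the lipid droplet gene PLIN2 at 187 and 60.7 CPM, the fatty acid transporter CD36 at 9.17 and 3.18 CPM, and the alcohol dehydrogenase ADH1B had 1202 UMIs against 7, a 212-fold difference (103 to 529) at a low level (7.11 and 0.0335 CPM). Of 4 osteogenic genes measured, from a list of 14, BMP4 (24.5 and 4.26 CPM) and TNFRSF11B (640 and 268 CPM) were lower, with a median of -0.68. Only 5 chondrogenic genes were measured, from a list of 14. COMP, MATN3 (3.73 and 9.22 CPM), HAPLN1 (8.82 and 17.5 CPM) and SOX9 (12.3 and 22.9 CPM) were higher and SOX5 (35.9 and 10.8 CPM) lower, with a median of 0.99. Of 14 mesenchymal stromal identity genes, 4 were lower and none higher, with a median of -0.46, or -0.31 with TMM factors and -0.27 with median-of-ratios factors. These 4 were PDGFRA (182 and 82.4 CPM), S100A4 (2236 and 1193 CPM), NT5E, which encodes the surface antigen CD73 (282 and 154 CPM), and vimentin, VIM (8150 and 5109 CPM). Of 13 adipose progenitor genes, 4 were higher (PI16, at 10.1 and 75.0 CPM, CD55, at 62.9 and 166 CPM, ACKR3 and SEMA3C) and 3 lower (ALDH1A3, at 42.8 and 6.92 CPM, DPP4, at 206 and 70.6 CPM, and WNT2). Their median was -0.08, 0.10 with TMM factors, 0.01 after thinning and -0.18 over members at 1 CPM or more. PI16 was seen in 3.81% of untreated and 20.3% of TGFB1 cells after thinning (7.21% and 27.0% before).

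Secreted growth factors differed in both directions, with 8 of 23 members higher, 8 lower and a median of 0.09. It was -0.01 over members at 20 CPM or more, 0.22 over those at 1 CPM or more and 0.21 without 3 small clusters of the authors' cell table, numbered 7, 9 and 10. Besides HGF, FGF5 was lower at 106 and 28.5 CPM, whereas IGFBP3 was higher at 1132 and 4184 CPM and FGF18 at 3.39 and 10.4 CPM. Of 15 Wnt pathway genes, 5 were lower and 1 higher, with a median of -0.26, or -0.11 without clusters 7, 9 and 10 and -0.10 with equal weight per cell. The lower ones were RSPO3 (83.5 and 30.4 CPM), WNT2 (83.7 and 30.7 CPM), SFRP1 (606 and 308 CPM), WNT2B and ROR2, and the higher one was the receptor FZD8 (2.20 and 11.3 CPM). Of the Notch pathway, NOTCH2 (61.8 and 69.0 CPM) and HES4 (4.74 and 10.3 CPM) were measured. Regulators of epithelial-mesenchymal transition had 3 of 12 members higher and 5 lower, with a median of -0.17, or 0.02 with median-of-ratios factors. SNAI1 was at 2.83 and 11.3 CPM, TCF4 at 229 and 504 CPM, TWIST2 at 791 and 215 CPM and KLF4 at 28.1 and 8.36 CPM. The remaining ones past 1.5-fold were CDH2 (higher) and TWIST1, HMGA2 and SNAI2 (lower).

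Cell cycle genes were lower with TGFB1. All 21 G2 and M phase genes measured were at least 1.5-fold lower, with a median of -1.40. The topoisomerase TOP2A was at 49.5 and 12.5 CPM, CDC20 at 15.9 and 4.07 CPM, MKI67 at 28.3 and 8.07 CPM and NUSAP1 at 23.8 and 6.78 CPM. Of 16 S phase genes, 11 were lower and none higher, with a median of -0.84; thymidylate synthase, TYMS, was at 56.5 and 11.7 CPM. A UMI of MKI67 or TOP2A was seen in 11.8% (11.1 to 12.5) of untreated and 5.32% (4.87 to 5.79) of TGFB1 cells after thinning, and in 17.4% and 7.91% before. Without the cells holding such a UMI, the G2 and M phase median was -0.42 and the S phase median -0.32. The S phase median was -0.55 over members at 20 CPM or more. Of 16 senescence and p53 genes, CDKN2B and TP53I3 (122 and 241 CPM) were higher and 4 lower, with a median of -0.26, or -0.10 with TMM factors and -0.11 over members at 20 CPM or more. The lower ones were BTG2 (6.17 and 2.06 CPM), the lamin gene LMNB1 (8.77 and 3.13 CPM), FDXR and BBC3. CDKN1A, which encodes the cell cycle inhibitor p21, was at 160 and 158 CPM, a gene looked at after its values were seen.

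Metabolic and stress lists were mostly higher by small amounts. Glycolysis and hypoxia genes had 7 of 18 members higher and 1 lower, ADM, with a median of 0.56. The phosphofructokinase PFKP was at 63.5 and 174 CPM, the glucose transporter SLC2A1 at 7.03 and 16.6 CPM and VEGFA at 39.2 and 81.1 CPM. The integrated stress response and serine or proline synthesis list had 6 of 15 members higher and none lower, with a median of 0.42. The amino acid transporter SLC7A5 was at 26.0 and 66.9 CPM. Endoplasmic reticulum folding genes had 3 of 16 members higher and none lower, with a median of 0.33, and these were DNAJB9 (29.8 and 66.6 CPM), the chaperone HSPA5 (246 and 378 CPM) and SEC61B. Cholesterol synthesis genes had 3 of 16 members higher (SQLE at 19.1 and 39.3 CPM, MSMO1 and IDI1) and 1 lower, LSS, with a median of 0.18, or 0.40 over members at 20 CPM or more. Immediate early and heat shock genes had 2 of 16 members higher, IER3 (103 and 397 CPM) and BAG3, and none lower, with a median of -0.10, or 0.05 with TMM factors.

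Over whole libraries, few markers of other cell types reached 5 CPM. Of 4 pericyte genes measured, RGS4 was higher and ABCC9 lower (75.6 and 33.1 CPM), with a median of -0.26. It was 0.13 with TMM factors, -0.01 after thinning and -0.08 without clusters 7, 9 and 10. The endothelial list had EGFL7 (13.1 and 7.96 CPM) and ERG (1.48 and 10.00 CPM), and the immune list CD68 (24.1 and 16.3 CPM). The epithelial and mesothelial list had KRT19 (675 and 191 CPM) and KRT18 (35.1 and 80.2 CPM). The melanocyte and Schwann list had MITF (46.5 and 15.5 CPM) and the skeletal muscle list ACTC1 (15.04 and 67.70 CPM).

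Set against 10000 random lists of the same size and mean expression, the medians of the SMAD, contractile, matrix, integrin and glycolysis lists lay at percentile 100 in these libraries. The G2 and M phase and S phase lists lay at percentile 0, the inflammatory and stromal identity lists at 0.01, and the interferon and adipogenic lists at 0.02 and 0.07. Further percentiles were 99.99 for the chondrogenic list, 99.95 for the integrated stress response list and 97.3 for collagen modification. Bone morphogenetic protein targets (85.9), growth factors (92.3), adipose progenitors (40.6), immediate early genes (32.2), pericyte markers (26.4), transition regulators (16.5) and senescence genes (6.60) lay within the range of most random lists, as did the interleukin 6 family (42.9). The other lists were TGFB ligands and receptors (99.8), YAP and SRF targets (99.9), cholesterol synthesis (99.7), endoplasmic reticulum folding (99.6), proteases (95.1), the Wnt pathway (3.65) and osteogenic genes (1.00).

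Within the TGFB1 library, IL11 was found across clusters and was uneven between cells. The authors' cell table assigns each cell to 1 of 11 unnamed clusters made on both libraries together. In the 8 clusters with at least 100 TGFB1 cells, IL11 was between 73.0 CPM (59.1 to 89.2) in cluster 10 and 231 CPM (221 to 241) in cluster 8. In cluster 8, all 5 proliferation markers fixed beforehand were detected and higher than in the other cells, so it was called proliferating. Cluster 3 held 183 CPM, cluster 4 held 160 CPM, cluster 5 held 125 CPM and cluster 0 held 110 CPM. Cluster 5 had a median of 2571 UMIs per cell. The smaller clusters 1, 2 and 6, with 56, 46 and 21 TGFB1 cells, held 26.0, 21.5 and 64.7 CPM. In the 113 TGFB1 cells of cluster 10, 5 of 6 pericyte markers fixed beforehand were at 5 CPM or more. Of these, NOTCH3 (31.2 CPM, against 2.65 CPM in the other TGFB1 cells) and RGS5 (12.9 and 2.64 CPM) were at least 2-fold above the other cells. The smooth muscle genes ACTG2 (34.2 and 0.101 CPM) and MYH11 (144 and 0.838 CPM) and the matrix gene MGP (1142 and 4.87 CPM) were higher there as well. No pericyte marker was among the 10 leading genes of cluster 10, and it was left unnamed. Most of these clusters come from 1 library and may be that library and not a cell type. At thinned depth, IL11 had a mean of 1.07 UMIs per TGFB1 cell and a variance 2.41 times the mean. The median of that ratio was 1.13 over 1023 genes of similar mean, and IL11 lay at percentile 97.8 among them. The 10% of TGFB1 cells with most IL11 held 44.0% of its UMIs, where the same UMIs dealt evenly over these cells put 30.1% in the top 10%.

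**Figure D3:**
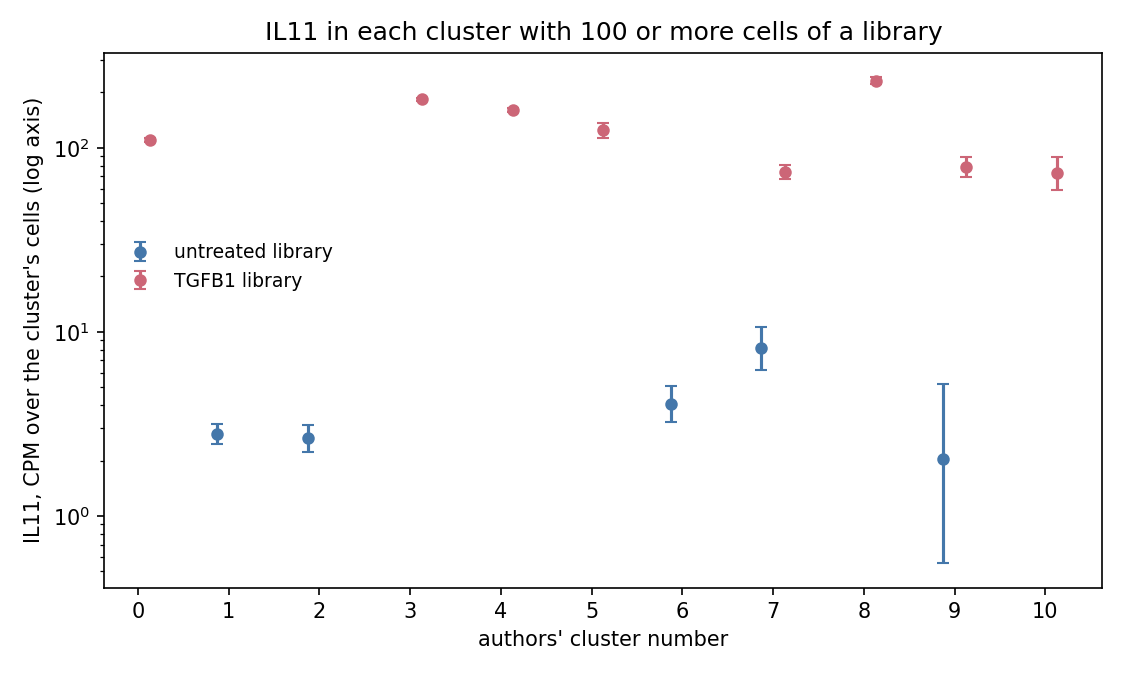
IL11 in CPM, on a log axis, over the cells of each of the authors' clusters, for every cluster and library with at least 100 cells, with exact 95% Poisson intervals for counting error. The TGFB1 points run from 73.0 to 231 CPM and the untreated points from 2.03 to 8.18 CPM.

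TGFB1 cells with and without an IL11 UMI were alike in most genes. After thinning there were 4861 cells with and 4469 without, and of 6051 genes at 20 CPM or more, 4 were at least 1.5-fold higher and 8 at least 1.5-fold lower in cells with IL11. The higher ones were the natriuretic peptide gene NPPB (1.75-fold, 1.55 to 1.98), the mitotic regulator CKS2 (1.51-fold), the immediate early gene NR4A1 (1.51-fold) and TSPAN13 (38.8 and 58.2 CPM). The next in order were MATN2 (1.44-fold), C11orf96, the endothelin gene EDN1 (1.39-fold), ENPP1, SEC14L2 and GABBR2. Without thinning, 6 of these 10 highest genes and 5 of the 10 lowest stayed among the 10, and 5 genes were at least 1.5-fold higher and 23 lower. The matrix inhibitor of calcification, MGP, had the lowest ratio at 0.380 (0.334 to 0.432), followed by ADAMTS1 (0.571), RSPO3 (0.617), CYP1B1 (0.636), NTN4 (0.652), POSTN (0.653), SFRP4 (0.659) and DEPTOR (0.661), then CLDN11 and CEMIP. Part of this order rested on small clusters with low IL11. Without clusters 7, 9 and 10 the ratio was 1.18 (0.912 to 1.54) for MGP, 0.956 for POSTN and 1.10 for SFRP4. The 4 genes then at least 1.5-fold lower were ADAMTS1 (0.574), RSPO3 (0.596), CLDN11 (0.645) and CYP1B1 (0.648), and the 2 higher ones were NPPB and TSPAN13. Of the 10 highest genes 9 remained among the 10. The G2 and M phase list had a median log2 ratio of 0.58 between these cells, the SMAD list 0.04 and the contractile list 0.06. Splitting cells on a detected UMI can leave many expressing cells among those without, at a mean of 1.07 UMIs. If all these cells expressed IL11 equally, 65.8% would show a UMI, against the 52.1% seen. The split can therefore hide differences between cells that express IL11 and cells that do not.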

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

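The settings that leave out cluster 5 or clusters 7, 9 and 10, the own clustering at resolution 0.5, the spread over clusters of any size and all settings for the 10 lowest genes were chosen after seeing the data. All 24 genes with the largest or smallest ratios kept their direction and stayed past 2-fold in all 8 settings that change scaling, cells or depth. They had been picked for extreme ratios in these data, so modest shifts could hardly bring them below 2-fold. Their stability says little about other genes. Of 29 list medians, 25 kept their sign with TMM factors, 24 with median of ratios, 28 with equal weight per cell, 28 after thinning and 29 in the other 4; the growth factor median changed sign from 20 CPM, to -0.01. Genes at least 2-fold higher and lower were 594 and 1227 from 1 CPM and 257 and 320 from 20 CPM, since other numbers of genes enter. The IL11 log2 ratio of 5.52 was 5.68 with TMM, 5.71 with median of ratios and 5.65 without clusters 7, 9 and 10. The IL11 share was 2.13% and 52.1% after thinning, and in TGFB1 cells 65.4% with the stricter cell filter, which removed 128 untreated and 329 TGFB1 cells, and 68.0% without cluster 5. Medians with TMM and median of ratios were 1.37 and 1.41 for SMAD genes, 1.04 and 1.08 for contractile genes, 0.61 and 0.65 for matrix genes and -1.25 and -1.21 for G2 and M phase genes. With equal weight per cell they were 0.94 (contractile), 0.41 (matrix) and -1.54 (G2 and M). Without clusters 7, 9 and 10 they were 1.30 (SMAD), 0.91 (contractile) and 0.46 (matrix), and after thinning 0.97 (contractile) and 0.44 (matrix). Without cells holding an MKI67 or TOP2A UMI they were 0.87 (contractile), 0.39 (matrix) and -0.42 (G2 and M), the last because the cells expressing these genes are removed. The contractile median was 0.79 from 1 CPM and the G2 and M median -1.52 from 20 CPM. Shares with an MKI67 or TOP2A UMI were 17.4% and 7.91% without thinning. Apart from these, the cause of a shift was not tested. Among TGFB1 clusters of 100 or more cells, the highest over the lowest IL11 level was 3.16 with the authors' clusters and 3.36, 2.76 and 2.87 with own clusters at resolution 0.3, 0.5 and 1. Over clusters of any size, down to 21 cells, it was 10.7 with the authors' clusters and 3.91, 7.99 and 7.31 with own clusters, so the spread depends on the size limit. The doublet setting removed no cell and gives no value. Depth limits genes below 5 CPM most, and the missing replicates limit every difference.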

Other observations

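The tests of cell composition, of cells read under the wrong library, of free RNA and of the untreated cluster were chosen after their patterns had been seen. Those of depth and of the interferon-induced genes were written down before.

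Clusters 7, 9 and 10 held cells of both libraries, which allows the libraries to be compared within a cluster, although the clusters were built on all genes, those that differ included. IL11 was higher with TGFB1 in each: 9.06-fold in cluster 7 (6.86 to 12.2), 38.9-fold in cluster 9 (15.001 to 143.8) and 54.0-fold in cluster 10 (9.47 to 2157, on 1 untreated UMI). PTX3 was lower in each, at 176 and 43.0 CPM in cluster 7, 500 and 99.5 CPM in cluster 9 and 393 and 48.7 CPM in cluster 10. ACTA2 was at 122 and 596 CPM in cluster 9, and at 3569 and 4574 CPM in cluster 10, where the untreated cells already held more than the TGFB1 library as a whole (1270 CPM). PI16 was at 262 and 390 CPM in cluster 9. LIF was at 7.30 and 7.04 CPM in cluster 7 (ratio 0.964, 0.632 to 1.47). It was 12.2-fold higher with TGFB1 in cluster 9 (1.95 to 506, on 1 untreated UMI) and 3.38-fold in cluster 10 (0.986 to 17.9, on 3 untreated UMIs).

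The share of cells with IL11 was 52.1% in the TGFB1 library against 2.13% at equal depth, so a difference in depth per cell cannot account for it. If the kinds of cells had changed and nothing else, IL11 would be at the same level in both libraries within a cluster. In clusters 7, 9 and 10, which hold 599 TGFB1 cells, the lowest lower bound of its ratio was 6.86. This argues against that for the TGFB1 cells of clusters 7 and 9. Cluster 10 weighs less, with only 33 untreated cells and 1 untreated IL11 UMI. Free RNA in the TGFB1 library, whose share could not be measured, could also raise IL11 in these clusters. The other 95.2% of TGFB1 cells lie in clusters of which, as with cluster 10, none has 100 cells of both libraries. In cluster 0, 16 untreated cells held IL11 at 8.44 CPM (1.74 to 24.7), against 110 CPM in its TGFB1 cells. In cluster 4, 11 untreated cells held 0 CPM (0 to 16.6) against 160 CPM, and cluster 3 had 0 untreated cells. On so few untreated cells, a change in the kinds of cells was not told apart from a change within cells there. A difference in handling between the libraries remains open, since each condition has 1 library.

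A set of 102 TGFB1 cells (0.812%) lay in clusters 1 and 2, which untreated cells fill. Their IL11 level, 26.0 CPM (17.4 to 37.3) in cluster 1 and 21.5 CPM (11.5 to 36.8) in cluster 2, was above the 2.80 and 2.64 CPM of untreated cells there. In the other direction, 63 untreated cells lay in clusters that TGFB1 cells fill. Cluster 6, also filled by untreated cells, held 21 TGFB1 cells at 64.7 CPM, which were left out of the set of 102. Cells of the untreated library read under the wrong one with their barcode kept are argued against, because 0 of the 102 barcodes occur in the untreated library. Untreated cells mixed in before barcodes were added would carry barcodes of their own, so mixing was not tested. Free RNA as the only source was tested on 31 strongly higher genes (at least 4-fold, 40 CPM or more), with over 25% of genes apart counting against it. In a first test, 41.9% lay apart from the median position of 13.3% between untreated and treated level, which passes that bound but assumes that free RNA has the makeup of treated cells. It was replaced, after both values were seen, by the ratio of gains between the clusters. Of the genes, 22.6% left that ratio beyond counting error (5% by chance). This share was above the lower share set for free RNA as the only source, yet short of the bound against it, so the test decided neither way. Free RNA therefore stays open, as do doublets and weakly responding cells.

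A hypothesis found and tested on the same cells, with no technical explanation tested, is that part of the untreated culture may hold the TGFB1 pattern without added TGFB1. Untreated cells were clustered without genes that differ between the libraries, and the cluster of 430 cells sharing most with the authors' cluster 7 (57.7% of its cells) was compared with the other untreated cells. Genes at least 2-fold higher with TGFB1 had a median log2 ratio of 0.60 there (84.3% of 249 genes up), and genes at least 2-fold lower one of -0.52 (82.5% of 308 down). These are smaller sets than the 395 and 661 genes counted from 5 CPM. The lower genes alone do not set it apart: over the other 6 clusters their median ran from -0.51 (in 1597 cells, 72.7% down) to 0.24, and that of the higher genes from -0.60 (in the same 1597 cells) to 0.19. IL11 was at 5.93 CPM (4.54 to 7.62) against 2.94 CPM (2.68 to 3.21), and another cluster, almost all proliferating cells of cluster 6, held 5.24 CPM (4.10 to 6.61). The genes leading the authors' cluster 7 among untreated cells were mixed. ACTC1 (202 against 7.13 CPM) and KRT18 (295 against 24.1 CPM) were higher in the TGFB1 library, but POSTN (2512 against 210 CPM) and SFRP4 (883 against 31.6 CPM) were not.

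The lower level of IFIT1, IFIT2 and IFIT3 in the TGFB1 library could stem from a small group of untreated cells responding to interferon. The 5% of untreated cells with most of these transcripts held 22.04% of their UMIs, against 14.8% if the transcripts were spread evenly by depth, which argues against a small group as the carrier of the difference.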
